A study of Mus musculus with 12 samples.

How the data were processed

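The samples were LSK cells sorted by flow cytometry from the bone marrow of C57BL/6 mice, wild type or Mll5-/-, with or without NAC in the drinking water. Total RNA was labelled with biotin and hybridised to 12 Affymetrix arrays, 3 for each of 4 groups. The values are log2 signals deposited by the authors, made with Affymetrix Power Tools and RMA per the submitters' processing notes, and versions are not given in the sources used here. RMA corrects background, normalises arrays by quantiles and summarises each probe set. The base of the logarithm is not stated and was taken from the range of the values, 0.74 to 13.23. Of 41345 probe sets, 25335 had an annotation, 23521 of them with 1 gene symbol, and 23328 of these matched a gene in the mouse reference table of assembly GRCm38.p6, with 0 symbols updated. The genome build of the array annotation is not named, so no coordinates are given and the reference served only for names and neighbouring genes. For each of 22180 symbols the probe set with the highest mean over all arrays was kept, with no filter on dim genes. The remaining 17824 probe sets without a single gene were tested only as an alternative.

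A model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by Benjamini-Hochberg over genes within each comparison, at 0.05. The comparisons were mutant against wild type in mock and in NAC, NAC against mock in the mutant and in wild type, their interaction, the mutant with NAC against wild-type mock, and the mean of each effect over both levels of the other factor. The replicate numbers do not pair the samples and were not used as a block. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with an estimated correlation. With the estimate, camera also refers its statistic to the 8 residual degrees of freedom, not to the number of genes. Its p-values are larger for this reason too. Of 31 lists, 30 had the minimum of 5 measured members; the sex-linked list had 4 and was not tested. A list's counts are given over all genes and adjusted over the list alone.

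Groups, comparisons, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Kmt2e, Bid, Ly6a and Kit. For the main comparisons, which are the genotype in mock, the genotype in NAC and NAC in the mutant, it named the 12 largest changes per direction past the threshold, or the 5 smallest p per direction where fewer than 5 passed. For the others it named the 5 largest per direction. It also named up to 4 members with the largest difference of each list that passed. Predicted or clone-named genes and immunoglobulin segments were left out of the rule but kept in the counts, and those named are said to be singled out. The alternatives fixed at that stage were a filter at the median level, array weights, centring on the median, a fresh quantile normalization, trend and robust variance, the mean of a symbol's probe sets, the replicate number as a block, only the compared groups, an adjusted p under 0.10, a minimum log2 difference of 0.5, an estimated correlation and leaving out each array in turn. Added after the data were seen were leaving out both arrays that stand apart, trend and robust variance together with the filter, all probe sets, list members on shared probe sets, and an exact permutation test of list means per array. The closing section gives their effect.

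The procedure was tested on simulated data, 5 simulations of 22180 genes with 200 changed genes each and the spread of these arrays. Changes of 1 on the log2 scale were found for 80.4% of genes between 2 groups and 95.6% over both treatments, and changes of 0.5 for 10.4% and 45.6%. These shares hold for 200 changed genes, since the adjustment is stricter where fewer genes change. The real mock comparison called 2 genes, so the shares do not measure how many changes of such sizes were missed there. All 15 lists shifted by 0.3 were found in each, with 1 call among 135 other lists. The simulated genes varied independently of each other. In the real arrays the estimated correlation was 0.594 within granulocyte and monocyte progenitor genes and 0.423 within lymphoid priming genes. The simulated list calls therefore do not measure how often camera makes false calls on these arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No array was left out, and the number of arrays, not a depth, limits the precision.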

Results

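Gene expression was measured on 12 arrays of LSK cells, the bone marrow fraction without lineage markers and with Sca1 and Kit on the surface, which holds haematopoietic stem cells and multipotent progenitors. The cells came from C57BL/6 mice that were wild type or lacked Mll5, a chromatin regulator gene now named Kmt2e, and that either went without NAC (mock) or had 1 g per liter of NAC, a quencher of reactive oxygen species, in their drinking water from the mating of their parents on. Each of the 4 groups had 3 arrays. The median log2 signal lay between 2.89 and 2.96 in every array, and pairs of arrays correlated at 0.976 to 0.988 across the tested genes. Wild-type mock replicate 1 and mutant NAC replicate 1 stood apart from the rest, with array weights of 0.71 and 0.54. The number of arrays limits the precision: the median standard error of a log2 difference between 2 groups was 0.16. The labels do not say whether the arrays of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

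The probe set of Kmt2e, the targeted gene, gave a log2 signal of 7.27 ± 0.30 (SD, n = 3) in mutant mock cells and 7.52 ± 0.15 in wild-type mock cells. With NAC it gave 7.12 ± 0.18 in the mutant and 7.55 ± 0.21 in wild type. The log2 difference between genotypes was -0.25 (SE 0.17, adjusted p = 0.843) in mock and -0.43 (SE 0.17, adjusted p = 0.664) in NAC, and over both treatments it was -0.34 (SE 0.12, adjusted p = 0.419). Neither the deleted part of the gene nor the part that the probe set reads is given, so these values do not check the genotype labels. AI506816, an uncharacterised gene that lies 2 measured genes past Kmt2e in the mouse annotation, fell by 2.53 on the log2 scale (SE 0.25, 5.79-fold, adjusted p = 0.00313) in mutant mock cells. Its signal was 3.82 ± 0.50 there and 6.35 ± 0.42 in wild type. In NAC its log2 difference was -1.80 (SE 0.25, adjusted p = 0.068), and over both treatments it fell by 2.17 (SE 0.17, adjusted p = 0.000331), with all 6 mutant arrays below all 6 wild-type arrays. Srpk2, a kinase of splicing factors and the measured gene next to Kmt2e on the same side, had a log2 difference of 0.63 over both treatments (SE 0.11, adjusted p = 0.105). AI506816 and Srpk2 were singled out after their values were seen.

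**Figure D1:**
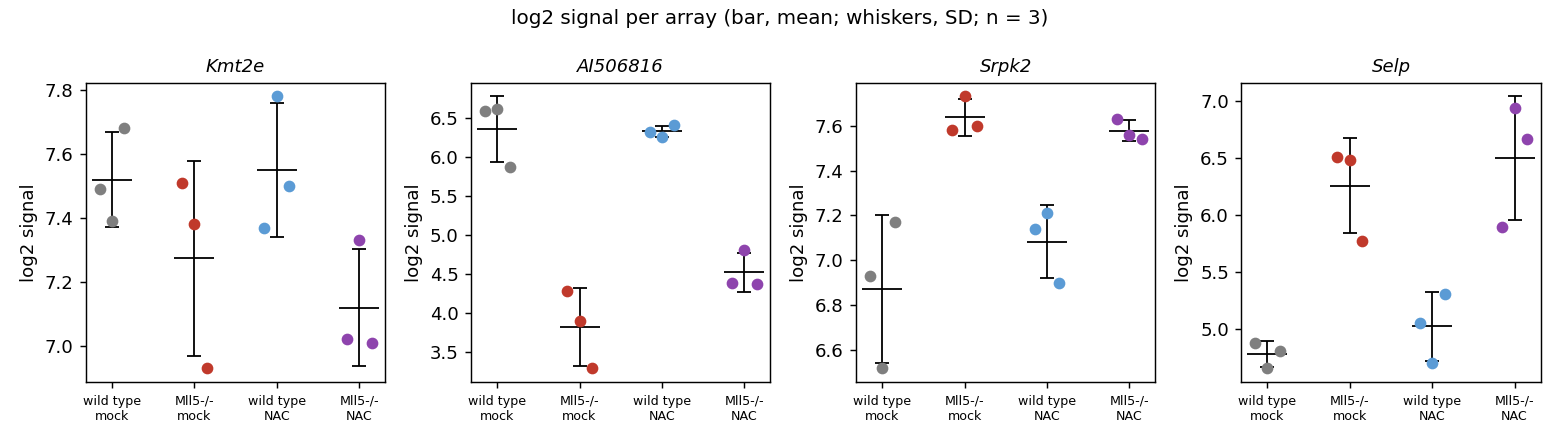
Log2 signal of Kmt2e, AI506816, Srpk2 and Selp on each array, by group (points, arrays; bar, mean; whiskers, SD; n = 3). AI506816 had a mean of 3.82 in mutant mock and 4.52 in mutant NAC arrays against 6.35 and 6.32 in the wild-type groups, and Selp a mean of 6.26 and 6.50 in the mutant groups against 4.78 and 5.03.

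The comparison of mutant and wild-type mock cells asked what the loss of Mll5 changes in LSK cells without NAC. Lymphoid priming genes, which mark the earliest steps toward lymphocytes, fell together: all 14 measured members were lower, with a median log2 difference of -0.39 (camera adjusted p = 8.89e-08, and adjusted p = 0.273 with an estimated correlation). Among them Dntt, the template-independent DNA polymerase of antigen receptor joining, had a log2 difference of -1.18 (SE 0.31) and Rag2, part of the recombinase, one of -1.15 (SE 0.46). Il7r, a cytokine receptor of lymphoid precursors, differed by -0.89 (SE 0.40) and Lax1, a membrane adaptor of lymphocytes, by -0.81 (SE 0.21). No member passed over all genes and 2 passed adjusted over the list alone. The groups overlapped in the list's mean per array: mutant mock replicate 3 (-0.211 from the wild-type mock mean) lay above wild-type mock replicate 1 (-0.319). Megakaryocyte genes rose by a median of 0.28, with 13 of 15 higher (adjusted p = 0.000712, and adjusted p = 0.0939 with an estimated correlation). Selp, the platelet adhesion molecule P-selectin, had a log2 difference of 1.48 (SE 0.26) and Itga2b, a platelet integrin, one of 0.42 (SE 0.17). Gp5, a platelet glycoprotein, differed by 0.48 (SE 0.31) and Thbs1, thrombospondin, by 0.61 (SE 0.60, and -0.07 without mutant mock replicate 1). Of the 15, 0 passed over all genes and 1 adjusted over the list alone. Immediate early and heat shock genes, which respond within minutes to growth signals and stress, fell by a median of 0.28 with 18 of 20 lower (adjusted p = 0.000199, and adjusted p = 0.273 with an estimated correlation). The transcription factors Klf4 and Egr1 had log2 differences of -0.70 (SE 0.24) and -0.69 (SE 0.27). The chaperones Hspa1b and Hspa1a had differences of -0.86 (SE 0.54) and -0.74 (SE 0.67). None of the 20 passed over all genes or adjusted over the list alone, and the list's median was -0.15 without mutant mock replicate 3 and -0.17 without wild-type mock replicate 3.

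Further groups also passed camera in mock cells. NF-kB and inflammatory genes fell by a median of 0.17, with 16 of 17 lower (adjusted p = 0.00223, and adjusted p = 0.273 with an estimated correlation). Among them were the chemokines Ccl4 (-0.66, SE 0.22), Ccl3 (-0.52, SE 0.20) and Cxcl2 (-0.53, SE 0.32) and the cytokine Tnf (-0.65, SE 0.31). G2 and M phase genes rose by a median of 0.19, with 19 of 22 higher (adjusted p = 0.000199, and adjusted p = 0.291 with an estimated correlation), including the mitotic kinesins Kif20a (0.47, SE 0.15) and Kif11 (0.38, SE 0.16). S phase genes rose by a median of 0.13, with 16 of 21 higher (adjusted p = 0.00185, and adjusted p = 0.273 with an estimated correlation), such as Rrm2, a subunit of ribonucleotide reductase (0.48, SE 0.18), and Pola1, a DNA polymerase subunit (0.37, SE 0.14). Haematopoietic stem cell genes rose by a median of 0.18, with 17 of 23 higher (adjusted p = 0.00859, and adjusted p = 0.291 with an estimated correlation), among them the receptors Tek (0.68, SE 0.26) and Procr (0.44, SE 0.19). Oxidative phosphorylation genes (0.12, 20 of 23 higher, adjusted p = 0.00487) and the BCL2 family and caspases (0.12, 16 of 20 higher, adjusted p = 0.0298) rose as well, with adjusted p = 0.291 and adjusted p = 0.273 with an estimated correlation. Bid, the apoptosis regulator in the title of the series, had a log2 difference of 0.41 (SE 0.14, adjusted p = 0.643), and Bcl2l11, a death-promoting relative, -0.52 (SE 0.20, adjusted p = 0.698). No member of these 6 groups passed over all genes or adjusted over the list alone. The calls of G2 and M phase, NF-kB and oxidative phosphorylation genes ended without wild-type mock replicate 3 (adjusted p = 0.147, 0.199 and 0.147), where their medians were 0.10, -0.12 and 0.04. That of stem cell genes ended without wild-type mock replicate 1 (0.392, median 0.08), that of S phase genes without mutant mock replicate 3 (0.0945), and that of the BCL2 family without mutant mock replicate 1 or wild-type mock replicate 3 (0.0599 and 0.106). Medians were 0.28 for stem cell genes without wild-type mock replicate 3, 0.20 for S phase genes without mutant mock replicates 1 or 2, and 0.19 for the BCL2 family without mutant mock replicate 2. Without wild-type mock replicate 2, 16 lists passed in place of 9.

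Single genes in mock cells were few. Of 22180 genes, limma called 2 at an adjusted p under 0.05, AI506816 and 1190005I06Rik, while 1471 had an unadjusted p under 0.05 where chance gives 1109. The uncharacterised 1190005I06Rik rose by 1.38 (SE 0.16, at least 2.61-fold, adjusted p = 0.0117), from a wild-type signal of 2.77 that lay under the median gene level of 3.17. Among named genes that did not pass, the smallest p of those higher in the mutant belonged to Cxcr2, a chemokine receptor of neutrophils (1.02), Selp, Clec2i, a lectin-like ligand of lymphocytes (1.16), Srpk2 (0.76) and Ms4a6b (0.91), with adjusted p from 0.291 to 0.358. Of those lower, it belonged to Chrnb1, an acetylcholine receptor subunit (-0.95), St3gal6, a sialyltransferase (-0.98), Zfp972 (-1.40), Cox6b2 (-0.81) and Sdc1, a heparan sulfate proteoglycan (-0.74), with adjusted p from 0.105 to 0.358. Kit differed by -0.09 (SE 0.11, adjusted p = 0.919), and Ly6a, which encodes Sca1, has no probe set of its own. Both calls ended when only the mock groups were fitted (adjusted p = 0.0733 for AI506816 and 0.0569 for 1190005I06Rik), where Jchain, a chain of secreted antibodies singled out for this reason, passed instead (-2.86, SE 0.21, adjusted p = 0.011). Its mutant mock signal of 2.66 lay under the median gene level, so the size of that fall is a lower bound. The calls of AI506816 and 1190005I06Rik also ended without both arrays that stand apart (0.0908 and 0.148). The call of 1190005I06Rik ended without mutant mock replicate 1 (adjusted p = 0.0607) and without wild-type mock replicates 1, 2 or 3 (0.103, 0.0958 and 0.0548). The count became 4 without mutant mock replicate 3, and 1 without mutant mock replicate 1 or wild-type mock replicate 1 or 2. Chrnb1 passed without mutant mock replicate 3 (adjusted p = 0.0406).

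The same comparison in mice that drank NAC asked which genotype differences are seen with the quencher. Lymphoid priming genes fell again, with all 14 lower and a median of -0.52 (adjusted p = 1.64e-09, and adjusted p = 0.192 with an estimated correlation); 0 passed over all genes and 6 adjusted over the list alone. Dntt had a log2 difference of -1.04 (SE 0.31), Il7r -1.01 (SE 0.40), Flt3, a cytokine receptor of early progenitors, -0.88 (SE 0.24) and Lax1 -0.83 (SE 0.21). Megakaryocyte genes rose by a median of 0.36, with 14 of 15 higher (adjusted p = 8.11e-07, and adjusted p = 0.0121 with an estimated correlation), and 5 passed adjusted over the list alone and 0 over all genes. Their largest differences were those of Selp (1.48, SE 0.26), the platelet chemokine Pf4 (1.41, SE 0.39), the receptor Treml1 (0.76, SE 0.20) and the tetraspanin Cd9 (0.68, SE 0.21). NF-kB and inflammatory genes fell by a median of 0.34, with 14 of 17 lower (adjusted p = 4.1e-05, and adjusted p = 0.141 with an estimated correlation). All 12 B cell genes were lower, with a median of -0.21 (adjusted p = 9.16e-05, and adjusted p = 0.119 with an estimated correlation). Blnk, an adaptor of B cell receptor signalling, had a log2 difference of -1.43 (SE 0.19, adjusted p = 0.068). Igll1, of the pre-B cell receptor, differed by -0.84 (SE 0.40) and Vpreb3 by -0.64 (SE 0.21). Of the list, 1 gene passed adjusted over the list alone. Immediate early and heat shock genes fell by a median of 0.24, with 16 of 20 lower (adjusted p = 0.000261, and adjusted p = 0.317 with an estimated correlation); 2 passed adjusted over the list alone. Egr1 differed by -0.99 (SE 0.27) and Nr4a1, an orphan nuclear receptor, by -0.75 (SE 0.20). Without mutant NAC replicate 3 the median of megakaryocyte genes was 0.22 (adjusted p = 5.22e-05) and that of B cell genes -0.34.

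Haematopoietic stem cell genes rose in NAC by a median of 0.20, with 18 of 23 higher (adjusted p = 0.0088, and adjusted p = 0.343 with an estimated correlation), among them Slamf1 (0.58, SE 0.30) and Fgd5 (0.52, SE 0.17). That call ended without mutant NAC replicate 2 (adjusted p = 0.0515, median 0.11). Oxidative phosphorylation genes rose by 0.18 (adjusted p = 0.016) and G2 and M phase genes by 0.08 (adjusted p = 0.0285), while NADPH oxidase genes fell by 0.18 (adjusted p = 0.016) and type I interferon sensors, ligands and receptor genes by 0.12 (adjusted p = 0.0191). With an estimated correlation these 4 groups had adjusted p = 0.349, adjusted p = 0.665, adjusted p = 0.349 and adjusted p = 0.235 in this order. Tlr7, a sensor of single-stranded RNA, had a log2 difference of -1.03 (SE 0.39), Cybb, the catalytic subunit of the phagocyte oxidase, -1.01 (SE 0.57) and Cox5b, a cytochrome oxidase subunit, 0.61 (SE 0.22). Oxidative phosphorylation lost its call without mutant NAC replicate 2 (0.134, median 0.09) or wild-type NAC replicate 1 (0.08, median 0.11), and G2 and M phase without mutant NAC replicate 3 (0.252) or wild-type NAC replicates 1 or 3 (0.145 and 0.0569). NADPH oxidase lost it without mutant NAC replicate 1 (0.394, median -0.05) or wild-type NAC replicate 3 (0.0594), and interferon sensors without mutant NAC replicate 1 (0.0706) or wild-type NAC replicates 2 or 3 (0.0723 and 0.0897, medians -0.20 and -0.06).

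No single gene passed limma's test between the genotypes in NAC, and 1590 had an unadjusted p under 0.05. The smallest p of named genes higher in the mutant belonged to Selp, the lipid carrier Apoe (0.61), Clca3a1 (0.89), Mrps22, a mitochondrial ribosome protein (0.65), and Ndrg2 (0.92), with adjusted p from 0.305 to 0.457. Of those lower, it belonged to Blnk, Fcrl1, a receptor-like protein of B cells (-0.75), the zinc transporter Slc30a4 (-0.74), Sipa1l2 (-0.63) and Zfp513 (-1.02), with adjusted p from 0.068 to 0.457. Bid differed by -0.13 (SE 0.14) and Kit by -0.25 (SE 0.11, adjusted p = 0.689). The count was 3 without wild-type mock replicate 3 and 1 without mutant NAC replicate 1, mutant mock replicate 3 or wild-type NAC replicates 2 or 3. Blnk passed without wild-type NAC replicate 2 (adjusted p = 0.0258) or wild-type mock replicate 3 (0.0379), and AI506816 without mutant mock replicate 3 (0.0343) or wild-type mock replicate 3 (0.0379).

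Over both treatments, 6 mutant against 6 wild-type arrays, limma called AI506816 and Selp. Selp rose by 1.48 (SE 0.19, 2.78-fold, adjusted p = 0.0269), with every mutant array above every wild-type array. Megakaryocyte genes rose by a median of 0.29, with 14 of 15 higher (adjusted p = 1.22e-07, and adjusted p = 0.00814 with an estimated correlation). Of them 1, Selp, passed over all genes and 7 passed adjusted over the list alone. Lymphoid priming genes fell by a median of 0.45, with all 14 lower (adjusted p = 8.85e-13, and adjusted p = 0.0986 with an estimated correlation), and 9 passed adjusted over the list alone and 0 over all genes. An exact permutation test of each list's mean per array, chosen after the data were seen, used 400 arrangements within treatment and gives a two-sided p of at least 0.005. In it 7 of 30 lists passed at an adjusted p of 0.0429, and 11 had an unadjusted p under 0.05. Lower in the mutant were lymphoid priming (-0.53), B cell (-0.29), immediate early and heat shock (-0.28), NF-kB (-0.27) and interferon sensor genes (-0.14). Megakaryocyte (0.39) and oxidative phosphorylation genes (0.12) were higher. In camera with an estimated correlation, B cell and NF-kB genes had adjusted p = 0.0854 each, immediate early and interferon sensor genes adjusted p = 0.125 each and oxidative phosphorylation genes adjusted p = 0.169. Across genes, which are not independent replicates, the genotype differences in mock and in NAC correlated at r = 0.24 (rho = 0.18), and 1 of 200 arrangements of the labels, the real one, gave a value as large (one-sided permutation p = 0.005, the smallest possible; adjusted p = 0.005 over 2 relations). The call of Selp ended without wild-type mock replicates 1, 2 or 3 (adjusted p = 0.0949, 0.0751 and 0.0768) or mutant mock replicates 1 or 2 (0.136 and 0.0939). It also ended without wild-type NAC replicates 1 or 2 (0.12 and 0.0903) or mutant NAC replicates 2 or 3 (0.0781 and 0.0907). The count of 2 became 1 without these arrays, except wild-type mock replicates 2 and 3. It became 5 without mutant NAC replicate 1 and 7 without mutant mock replicate 3, where Dntt passed (adjusted p = 0.0237).

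**Figure D2:**
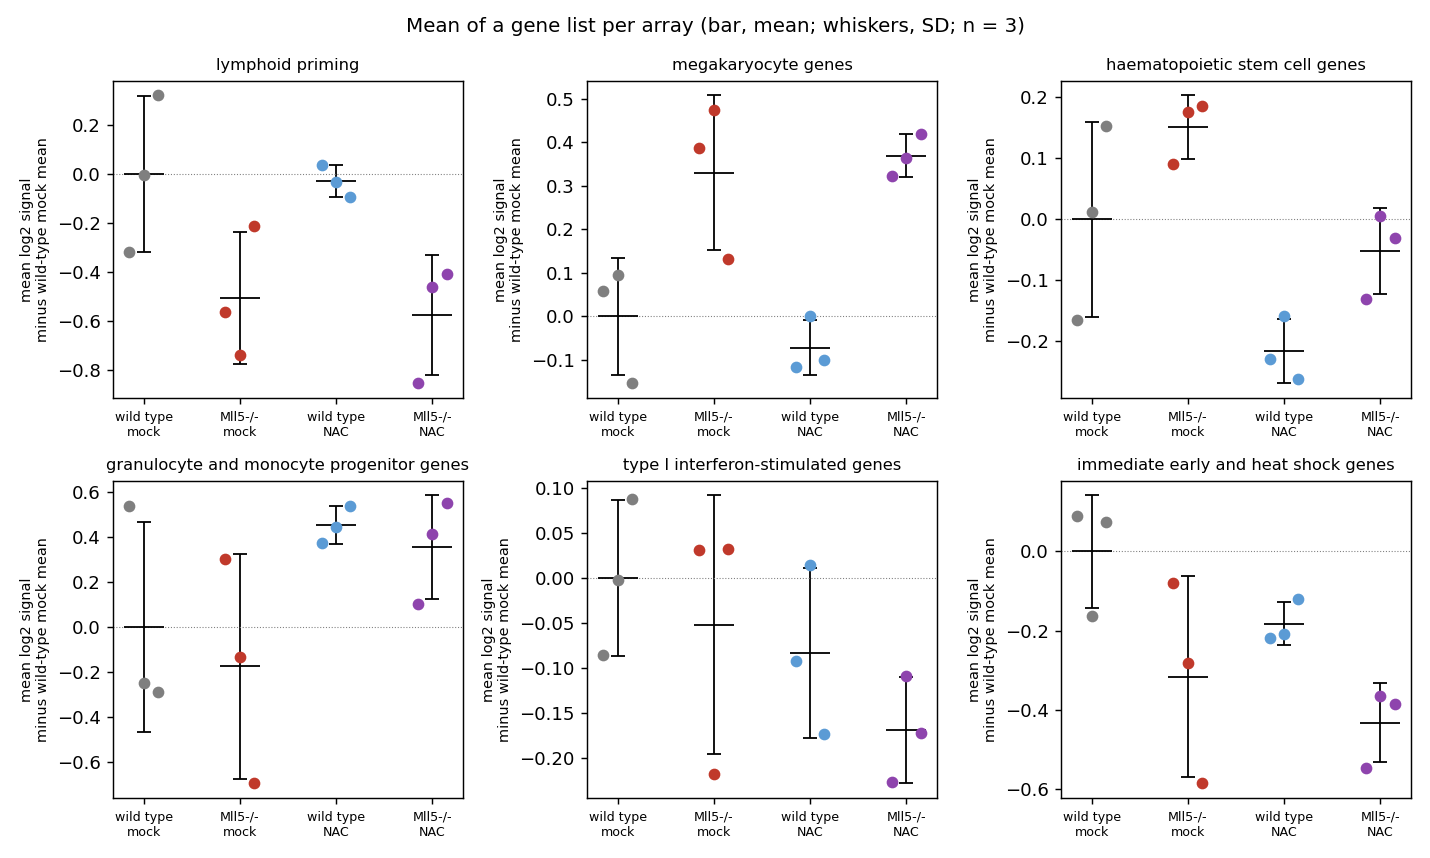
Mean log2 signal of 6 gene lists on each array minus the mean of the wild-type mock arrays, by group (points, arrays; bar, mean; whiskers, SD; n = 3). Lymphoid priming genes were lower and megakaryocyte genes higher in the mutant groups with and without NAC, and in the granulocyte and monocyte progenitor list the mock arrays spread widely in the mutant (SD 0.50) and in wild type (SD 0.47).

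NAC against mock in the mutant asked what the quencher changes in cells without Mll5. Granulocyte and monocyte progenitor genes rose by a median of 0.54, with 13 of 17 higher (adjusted p = 2.77e-05, and adjusted p = 0.394 with an estimated correlation). The mutant mock arrays spread widely in this list, with replicate 1 above mutant NAC replicate 1, and without mutant mock replicate 3 its median was 0.26 (adjusted p = 0.0212). The largest differences were those of Igsf6 (1.43, SE 0.54), Ms4a3, a marker of granulocyte and monocyte progenitors (1.42, SE 0.43), the Fc receptor Fcgr3 (1.16, SE 0.37) and Ly86 (0.94, SE 0.39). Mast cell, basophil and eosinophil genes rose by a median of 0.45, with 9 of 11 higher (adjusted p = 0.000495, and adjusted p = 0.308 with an estimated correlation). Among them were Prg3, an eosinophil granule protein (1.01, SE 0.27), Hdc, which makes histamine (0.94, SE 0.37), and Fcer1a, the IgE receptor chain (0.85, SE 0.19), and 2 passed adjusted over the list alone. Their median was 0.27 without mutant mock replicate 2, 0.26 without mutant NAC replicate 1 and 0.75 without mutant NAC replicate 3. Haematopoietic stem cell genes fell by a median of 0.14, with 19 of 23 lower (adjusted p = 0.000495, and adjusted p = 0.376 with an estimated correlation). Among them were Meis1, a homeobox factor of stem cells (-0.52, SE 0.15), Robo4 (-0.70, SE 0.27) and Procr (-0.50, SE 0.19). Type I interferon-stimulated genes fell by a median of 0.11, with 32 of 44 lower (adjusted p = 0.0267, and adjusted p = 0.394 with an estimated correlation). Of these, Oas2, an antiviral enzyme, differed by -0.91 (SE 0.32), and Mx2, an antiviral GTPase, by 0.45 (SE 0.18). MHC class I genes fell by a median of 0.15, with 12 of 14 lower (adjusted p = 0.0267, and adjusted p = 0.308 with an estimated correlation), such as their activator Nlrc5 (-0.45, SE 0.17). No member of these 5 groups passed over all genes.

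Of the other groups in the NAC-treated mutant, G2 and M phase (0.10, adjusted p = 0.0223), oxidative phosphorylation (0.07, adjusted p = 0.0281) and macrophage and dendritic cell genes (0.17, adjusted p = 0.0284) rose and immediate early and heat shock genes fell by 0.14 (adjusted p = 0.0353). With an estimated correlation they had adjusted p = 0.394 to 0.465. Igkj1, a joining segment of the immunoglobulin kappa light chain and the 1 gene limma called, rose by 2.98 (SE 0.31, at least 7.91-fold, adjusted p = 0.00618), from a log2 signal of 2.53 ± 0.06 (SD, n = 3) to 5.52 ± 0.50. The mock signal lay under the median gene level of 3.17, close to background, so folds of Igkj1 are lower bounds. It was singled out after its values were seen, and 1299 genes had an unadjusted p under 0.05. The smallest p of other named genes higher with NAC belonged to Spib, a transcription factor of B cells and plasmacytoid dendritic cells (0.81), Trem3, a receptor of myeloid cells (1.70), Gatm, of creatine synthesis (0.82), Rabl2 (0.83) and the helicase Dhx29 (0.88), with adjusted p from 0.184 to 0.406. Of those lower, it belonged to the serotonin receptor Htr2a (-1.19), Zfp942 (-1.12), the Polycomb protein Phc1 (-0.63), Emcn, a sialomucin of stem and endothelial cells (-0.99), and Prrg4 (-0.94), with the same range. Bid differed by 0.04 (SE 0.14; -0.003 without mutant mock replicate 1 and -0.03 without mutant NAC replicate 2) and Kit by -0.30 (SE 0.11, adjusted p = 0.809). Igkj1 lost its call without mutant mock replicates 1, 2 or 3 (adjusted p = 0.0681, 0.0587 and 0.0568) or mutant NAC replicate 1 (0.0532), where the count was 0. The count was 2 without mutant NAC replicate 3, wild-type NAC replicate 3 (1190005I06Rik passed, 0.0206) or wild-type mock replicate 2 (Trem3 passed, 0.025). It also lost its call without both arrays that stand apart (0.0588). List calls ended for MHC class I without mutant NAC replicate 1 (0.115, median -0.08), for G2 and M phase without mutant NAC replicate 3 or mutant mock replicates 2 or 3 (0.162, 0.0502 and 0.0699), and for oxidative phosphorylation without mutant NAC replicate 2 or mutant mock replicate 2 (0.185 and 0.108). They also ended for macrophage genes without mutant NAC replicates 1 or 2 or mutant mock replicates 2 or 3 (0.115, 0.0534, 0.0502 and 0.133), and for immediate early genes without mutant NAC replicates 1 or 3 or mutant mock replicates 1 or 2 (0.278, 0.0568, 0.507 and 0.0588). The median of macrophage genes was 0.11 without mutant NAC replicate 1 and 0.27 without mutant mock replicate 3. That of immediate early genes was -0.02 and -0.27 without mutant NAC replicates 1 and 2, and -0.09 and -0.23 without mutant mock replicates 1 and 3.

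In wild-type cells the comparison of NAC with mock asked what the quencher does where Mll5 is present. Granulocyte and monocyte progenitor genes rose by a median of 0.53, with 16 of 17 higher (adjusted p = 5.61e-05, and adjusted p = 0.521 with an estimated correlation). The groups overlapped in this list's mean per array: wild-type mock replicate 1 (0.536 from the wild-type mock mean) lay above wild-type NAC replicates 1 and 2 (0.371 and 0.443). S phase genes rose by 0.20, with 19 of 21 higher (adjusted p = 3.56e-05, and adjusted p = 0.428 with an estimated correlation), and G2 and M phase genes by 0.21, with 21 of 22 higher (adjusted p = 6.24e-05, and adjusted p = 0.521 with an estimated correlation). Haematopoietic stem cell genes fell by a median of 0.18, with 21 of 23 lower (adjusted p = 0.000196, and adjusted p = 0.491 with an estimated correlation). Csf1r, the receptor of macrophage colony-stimulating factor, had a log2 difference of 0.85 (SE 0.33) and Gins1, of the replicative helicase, one of 0.59 (SE 0.16). Plk1, a mitotic kinase, differed by 0.40 (SE 0.14) and Hlf, a transcription factor of stem cells, by -0.43 (SE 0.17). Oxidative phosphorylation (0.11, adjusted p = 0.0186) and NADPH oxidase genes (0.25, adjusted p = 0.04) rose and immediate early and heat shock genes fell by 0.17 (adjusted p = 0.0286), each at adjusted p = 0.521 with an estimated correlation. No member of these lists passed over all genes or adjusted over the list alone. Igkj1 rose by 4.62 (SE 0.31, at least 24.6-fold, adjusted p = 3.44e-05), to a log2 signal of 7.45 ± 0.46 (SD, n = 3) from 2.83 ± 0.60. Gprc5b, an orphan G protein-coupled receptor, fell by 1.19 (SE 0.15, adjusted p = 0.0291), and 1313 genes had an unadjusted p under 0.05.

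The wild-type lists leaned on wild-type mock replicate 3, without which 1 list passed in place of 7. Granulocyte and monocyte progenitor, G2 and M phase, stem cell, oxidative phosphorylation, NADPH oxidase and immediate early genes then had adjusted p of 0.0569, 0.135, 0.109, 0.244, 0.232 and 0.459, and medians of 0.27, 0.11, -0.08, 0.08, 0.18 and -0.12. Without wild-type mock replicate 1, 12 lists passed, with medians of 0.12 for S phase and -0.29 for stem cell genes. Without wild-type mock replicate 2 the medians were 0.27 for granulocyte and monocyte progenitor (adjusted p = 0.00761) and 0.16 for oxidative phosphorylation genes. NADPH oxidase genes also lost their call without wild-type mock replicate 2 or wild-type NAC replicates 2 or 3 (0.366, 0.0527 and 0.15, medians 0.16, 0.22 and 0.13), oxidative phosphorylation without wild-type NAC replicate 2 (0.145) and immediate early genes without wild-type NAC replicates 2 or 3 (0.0615 and 0.0582). Gprc5b lost its call without wild-type mock replicates 2 or 3 (adjusted p = 0.241 and 0.177), wild-type NAC replicates 1 or 3 (0.176 and 0.199), mutant NAC replicate 2 (0.0746) or mutant mock replicates 1 or 3 (0.0533 and 0.0509). Its call also ended when only the wild-type groups were fitted (0.187). Leaving out these arrays left 1 gene, except without wild-type NAC replicate 3, and 5 genes passed without wild-type NAC replicate 2, mutant NAC replicate 3 or mutant mock replicate 2.

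Over both genotypes NAC raised Igkj1 by 3.80 (SE 0.22, at least 13.9-fold, adjusted p = 5.33e-06), the 1 gene limma called, with all 6 NAC arrays above all 6 mock arrays; 1648 had an unadjusted p under 0.05. Granulocyte and monocyte progenitor genes rose by a median of 0.47, with 15 of 17 higher (adjusted p = 2.98e-08, and adjusted p = 0.284 with an estimated correlation), and 8 passed adjusted over the list alone and 0 over all genes. Their median was 0.30 without mutant mock replicate 3. Haematopoietic stem cell genes fell by a median of 0.16, with 20 of 23 lower (adjusted p = 9.16e-07, and adjusted p = 0.269 with an estimated correlation), and 3 passed adjusted over the list alone. All 22 G2 and M phase genes (0.15, adjusted p = 7.06e-06) and all 21 S phase genes (0.12, adjusted p = 2.81e-05) were higher, with adjusted p = 0.284 and adjusted p = 0.269 with an estimated correlation. In the exact permutation test of list means per array, 0 of 30 lists passed and 8 had an unadjusted p under 0.05 (smallest adjusted p = 0.15). Across genes, the NAC differences in the mutant and in wild type correlated at r = 0.20 (rho = 0.13), and 1 of 200 arrangements, the real one, gave a value as large (one-sided permutation p = 0.005, adjusted p = 0.005). The count of genes was 4 without mutant NAC replicate 3, where Jchain (adjusted p = 0.0431) and an immunoglobulin kappa variable gene (6.12e-05) passed, and 2 without wild-type NAC replicate 3.

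The interaction asked whether the genotype difference depends on NAC. No gene passed limma's interaction test (smallest adjusted p = 0.243, and 934 had an unadjusted p under 0.05 where chance gives 1109), and 0 of 30 lists passed camera. 1190005I06Rik, called in mock cells and at -0.03 (SE 0.16) in NAC, had an interaction of -1.41 (SE 0.23, adjusted p = 0.359). Igkj1 had one of -1.64 (SE 0.44, adjusted p = 0.999), and AI506816 one of 0.73 (SE 0.35, adjusted p = 0.999). The value of Igkj1 subtracts NAC effects that are each lower bounds, so its true size and direction are not fixed. Neither the genes nor the lists called in 1 group and not in another were therefore shown to differ between the groups. Without wild-type NAC replicate 3, 2 genes passed, and without wild-type mock replicate 2, 2 lists did.

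Interferon signalling is named in the title of the series. The 44 measured type I interferon-stimulated genes had a median log2 difference between genotypes of -0.05 in mock (17 higher, 27 lower, adjusted p = 0.287; 0.02 without mutant mock replicate 2) and -0.10 in NAC (13 higher, 30 lower, adjusted p = 0.105), and 0 of them passed over all genes or adjusted over the list alone. The list's interaction was -0.05 (adjusted p = 0.769). With NAC over both genotypes the list fell by a median of 0.08, with 31 of 44 lower (adjusted p = 0.00586, and adjusted p = 0.331 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. The list passed in NAC as lower in the mutant without mutant NAC replicate 2 (adjusted p = 0.0451) or wild-type NAC replicate 3 (0.0299), and its interaction turned to 0.04, 0.007 and 0.004 without mutant mock replicate 1, wild-type mock replicate 1 or wild-type NAC replicate 2. Of the groups tied to the title's other themes, p53 targets had medians of -0.09 in mock (adjusted p = 0.0578) and 0.03 in NAC (adjusted p = 0.934), and DNA damage response and repair genes 0.07 (adjusted p = 0.0827) and -0.03 (adjusted p = 0.625). Antioxidant and NRF2 targets had medians of -0.03 (adjusted p = 0.892) and 0.07 (adjusted p = 0.132), and glutathione and cysteine metabolism genes -0.01 (adjusted p = 0.803) and 0.04 (adjusted p = 0.715). These medians compare the genotypes. For NAC against mock, antioxidant targets had medians of 0.06 in the mutant (camera adjusted p = 0.138) and -0.003 in wild type (0.915). Glutathione genes had 0.06 (0.276) and 0.10 (0.39).

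The mutant with NAC was set against wild-type mock cells to show how far the treated mutant lies from the untreated wild type. Limma called 7 genes, and 2330 had an unadjusted p under 0.05. Besides AI506816 (-1.83, SE 0.25, adjusted p = 0.0381) and Igkj1 (2.68, SE 0.31, adjusted p = 0.0204), Btg2, an inhibitor of proliferation, fell by 0.95 (SE 0.12, adjusted p = 0.0272). Lax1 fell by 1.46 (SE 0.21), Chrnb1 by 0.98 (SE 0.14) and Asb13 by 1.14 (SE 0.17, adjusted p = 0.0479), and Nudcd2 rose by 1.43 (SE 0.21, adjusted p = 0.0471, as for Lax1 and Chrnb1). Of the 30 lists 14 passed, 8 of them higher and 6 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.0973). Lymphoid priming genes (-0.49, adjusted p = 3.72e-08, and adjusted p = 0.137 with an estimated correlation) and immediate early and heat shock genes (-0.44, adjusted p = 1.73e-07, and adjusted p = 0.0973 with an estimated correlation) fell. All 22 G2 and M phase genes were higher (0.29, adjusted p = 3.72e-08, and adjusted p = 0.16 with an estimated correlation). Interferon-stimulated genes fell by a median of 0.20, with 31 of 44 lower (adjusted p = 0.00239, and adjusted p = 0.254 with an estimated correlation), and 9 of them had an unadjusted p under 0.05. The count of genes was 15 without wild-type mock replicate 1, 3 without wild-type mock replicate 3 or mutant mock replicates 1 or 2, and 2 without mutant NAC replicate 2 or wild-type NAC replicate 3. It was 1 without mutant NAC replicate 1 or wild-type NAC replicates 1 or 2, and 0 without wild-type mock replicate 2, and adjusted p reached 0.15 for Asb13 without mutant NAC replicate 1. Fitted on these 2 groups alone the count was 0, with adjusted p from 0.211 to 0.221 for the 7 genes.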

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

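The tests of explanations, the splits of the arrays and the test of all probe sets were chosen only after the result was seen.

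AI506816, a near neighbour of the targeted gene, was lower in mutant arrays of both treatments. Arrays that stand apart are argued against as the cause, since it passed without both of them (adjusted p = 0.012 over both treatments, -2.08 against -2.17), although with fewer arrays its call in mock ended (adjusted p = 0.0908, -2.42 against -2.53). A change across the chromosome segment around Kmt2e, as a targeted allele or its flanking strain sequence may bring, stays open: the mean absolute t of 49 neighbouring genes was 1.11 against a median of 1.01 in 10000 random windows, and a share of 0.211 of the windows was as large. A biological effect of Mll5 loss on the gene was not tested apart from this, since every mutant array carries the same allele.

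Lymphoid priming genes were lower in mutant arrays of both treatments. Without both arrays that stand apart, their median over both treatments was -0.45 with a camera adjusted p of 1.95e-13 at the preset correlation. The fall over both treatments thus kept its size, but within each treatment its size depended on those arrays. Without them the median was -0.537 in mock against -0.385 with them, and -0.407 in NAC against -0.515. The list's estimated correlation was 0.423, with which camera gave an adjusted p of 0.0986 over all arrays, so the small p overstates the certainty. Fewer B cells carried through the sort, which selects against lineage markers, could give such a fall: the 6 B cell genes at or above the median level ranged from -0.77 (Igll1 and Blnk) to -0.07 (Cd79b) and -0.04 (Pax5) with a median of -0.42, all 12 B cell genes had a median of -0.20, and the 14 lymphoid priming genes had one of -0.45 (permutation p = 0.925 against the 6). The spread among the 6 leaves this test weak, and it does not separate fewer B cells from fewer or less primed lymphoid progenitors within the sorted cells, and both stay open.

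Igkj1 was higher with NAC in both genotypes. It passed without both arrays that stand apart (adjusted p = 0.000126 over both genotypes, and 0.0588 in the mutant alone), which argues against them as the cause. More plasma cells carried through the sort with NAC may contribute, since 16 plasma cell markers were shifted up (camera p = 0.0262 with an estimated correlation, median 0.10, 13 higher, 0 called) and 12 of 13 kappa variable and constant genes were higher (median 0.95). The markers ranged from -0.04 (Sdc1) to 0.70 (Sdf2l1), with Fkbp11 at 0.49, Xbp1 at 0.07 and Mzb1 at -0.007, and the high baseline of some and the low level of others would hide a small share, so the explanation stays open. Jchain and Ighm had differences of 1.93 (adjusted p = 0.258) and 1.11 (adjusted p = 0.401), and no biological explanation was tested. That of Jchain is a lower bound, since its mutant mock signal lay under the median gene level.

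Probe sets without a single gene name lie outside the genes compared, and some of them passed when all 41345 were tested. They numbered 1 between the genotypes in mock, 5 between the genotypes in NAC, 4 for NAC in wild type, 1 for the mutant with NAC against wild-type mock and 1 for the genotype over both treatments. Probe set 17547865 was higher in the mutant by 3.46 in mock (adjusted p = 0.00246), 3.11 in NAC (adjusted p = 0.00361) and 3.29 over both (SE 0.18, adjusted p = 0.000125). Probe set 17284402 was lower in the mutant in NAC (-5.50) and higher with NAC in wild type (5.50), and 17459392 likewise (-4.25 and 4.42). Both differences of a probe set share the wild-type NAC arrays. The mean levels over all arrays were 4.04 and 3.15, so with differences this large the low groups lie near background and the sizes are lower bounds.

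With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split and the highest other gave these counts of genes: 2 and 0 for the genotype in mock, 0 and 0 for the genotype in NAC (10 of 10 splits as large), 1 and 0 for NAC in the mutant, 2 and 0 for NAC in wild type, and 7 and 3 for the mutant with NAC against wild-type mock. The counts of lists were 9 and 12 (2 of 10 splits as large), 10 and 4, 9 and 4, 7 and 7 (2 of 10) and 14 and 10 in the same order. Where no number is given 1 split, the real one, was as large. For the genotype over both treatments, 100 of 200 possible splits were run, and 1, the real one, gave as many genes (2, highest other 1). That share is under 0.05. It rests on 2 genes against 1 and was not adjusted over the counts compared, so it is not taken to exclude chance. As many lists were given by 5 of the 100 (12, highest other 16), so chance is not excluded for that count of camera calls. With an estimated correlation 1 of the 100, the real one, gave a list (1, highest other 0), a difference too small to exclude chance by itself. In the exact permutation test 7 of 30 lists passed (adjusted p = 0.0429). For NAC over both genotypes 5 of 100 gave as many genes (1, highest other 1), where chance is not excluded. There 4 of 100 gave as many lists (10, highest other 16), a share under 0.05, but 3 other splits gave more than the real one, 0 lists passed with an estimated correlation and 0 of 30 passed the exact permutation test, so the list count is not taken to exclude chance. For the interaction all 100 gave as many genes (0, highest other 1) and lists (0, highest other 16). A real count of 0 makes every split as large, so the splits do not test these counts or the gene count of the genotype in NAC. The splits with 16 lists had 0 with an estimated correlation. Camera's preset correlation of 0.01 lay under the estimates for granulocyte and monocyte progenitor (0.594), lymphoid priming (0.423) and G2 and M phase genes (0.33). It lay above that for megakaryocyte genes (-0.009). A preset under the real correlation makes camera p-values too small, so those at the preset are read with those at the estimate. How much of the 16 this accounts for was not tested.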

How the results depend on the processing

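Leaving out both arrays that stand apart, all probe sets, shared probe sets and the exact permutation test were added after the data were seen. So was trend and robust variance with the filter. Of 8688 alternatives of 397 named genes and lists, 8371 kept direction and threshold side, 271 no longer passed, 39 newly passed and 7 reversed. Most of the 397 had not passed before, so the 8371 do not measure how stable calls are. The counts of genes follow in the order genotype in mock (2), genotype in NAC (0), NAC in the mutant (1), NAC in wild type (2), the mutant with NAC against wild-type mock (7), genotype over both treatments (2) and NAC over both genotypes (1), naming only those that moved by over 1.5 times; unless the setting shows the cause, the cause was not tested. With the filter at the median level the genotype in NAC gave 2. Array weights gave 4 for the genotype in NAC, 2 for NAC in the mutant and 4 for the genotype over both treatments. Fitting only the compared groups, which leaves fewer arrays, gave 1 for the genotype in mock, which was Jchain in place of AI506816 (adjusted p = 0.0733) and 1190005I06Rik (0.0569), 1 in NAC (AI506816), 1 for NAC in wild type (Igkj1) and 0 for the mutant with NAC against wild-type mock. A fresh quantile normalization gave 2 for NAC in the mutant and turned the interferon interaction to 0.003. Centring on the median gave 3 for the mutant with NAC against wild-type mock. An adjusted p under 0.10, a looser threshold, gave 2 for the genotype in NAC, 3 for NAC in the mutant, 51 for the mutant with NAC against wild-type mock and 12 for the genotype over both treatments. Without both arrays that stand apart the counts were 0 for the genotype in mock, 0 for NAC in the mutant, 0 for the mutant with NAC against wild-type mock, 4 for the genotype over both treatments and 3 for NAC over both genotypes, and 13 lists passed for NAC in wild type. There AI506816 differed by -2.42 (adjusted p = 0.0908) in mock and Igkj1 by 2.75 (0.0588) for NAC in the mutant. Trend and robust variance with the filter gave 3 for the genotype in NAC and 58 for the mutant with NAC against wild-type mock. Over all probe sets the counts were 5 for the genotype in NAC, 0 for NAC in the mutant, 5 for NAC in wild type and 1 for the mutant with NAC against wild-type mock. The replicate block gave 1 for the genotype in mock, 4 for the mutant with NAC against wild-type mock and 1 for the genotype over both treatments; 0 of 18 same-number pairs correlated above 0.1 after removal of group means (-0.06 to 0.06), so the numbers do not pair the samples. An estimated correlation left 0 lists for the genotype in mock, 1 in NAC, 0 for NAC in the mutant, 0 in wild type, 0 for the mutant with NAC against wild-type mock, 1 for the genotype over both treatments and 0 for NAC over both genotypes. Other settings ended these list calls (adjusted p in brackets). For the genotype in mock they were BCL2 family genes with the filter (0.0842), trend, robust variance and filter (0.0722) and a fresh quantile normalization (0.0682), oxidative phosphorylation with that normalization (0.0574) and stem cell genes without both arrays that stand apart (0.415). For the genotype in NAC they were interferon sensors with the filter (0.0583) and without both arrays (0.0637), NADPH oxidase with array weights (0.0565) and without both arrays (0.293), and oxidative phosphorylation (0.0582) and G2 and M phase (0.0572) with fresh normalization. For NAC in the mutant MHC class I lost its call with the filter (0.0615) and without both arrays (0.105), and macrophage genes with the filter (0.0888), trend, robust variance and filter (0.0824) and without both arrays (0.0563). Immediate early genes lost theirs there with the filter (0.0888), trend, robust variance and filter (0.054), array weights (0.105), only the compared groups (0.0531), shared probe sets (0.127) and without both arrays (0.303). For NAC in wild type NADPH oxidase lost its call with the filter (0.198), trend, robust variance and filter (0.171) and fresh normalization (0.0539), and oxidative phosphorylation with the filter (0.0584) and fresh normalization (0.0601). For the genotype over both treatments NADPH oxidase lost its call with array weights (0.131) and without both arrays (0.604), and mature neutrophil genes with the filter (0.135), trend, robust variance and filter (0.105), array weights (0.0504) and without both arrays (0.315). For NAC over both genotypes mature neutrophil genes lost theirs with fresh normalization (0.0514) and the replicate block (0.0677). Leaving out each array in turn, the counts of genes ranged from 1 to 4, 0 to 3, 0 to 2, 1 to 5, 0 to 15, 1 to 7 and 1 to 4 in the order above, and 0 to 2 for the interaction. The counts of lists ranged from 6 to 16, 8 to 10, 7 to 10, 1 to 12, 10 to 14, 10 to 14 and 8 to 14, and 0 to 2 for the interaction. Kmt2e ranged from -0.37 to -0.08 in mock and from -0.54 to -0.32 in NAC, and the interferon list from -0.117 to 0.023 in mock, reversed without mutant mock replicate 2, -0.171 to -0.042 in NAC and -0.117 to 0.039 for the interaction. There it reversed to 0.039, 0.007 and 0.004 without mutant mock replicate 1, wild-type mock replicate 1 or wild-type NAC replicate 2. Reversed genes were Thbs1 (-0.073 in mock without mutant mock replicate 1, range -0.073 to 1.38 over the arrays left out), Bid (-0.003 and -0.028, range -0.028 to 0.127, for NAC in the mutant without mutant mock replicate 1 or mutant NAC replicate 2), Hspa1a (0.167, 0.107 and 0.167, range -1.19 to 0.167, for NAC in wild type without wild-type mock replicate 1, wild-type NAC replicate 1 or both arrays that stand apart) and Bcl3 (0.035 for the mutant with NAC against wild-type mock without both arrays). The median gene level was 3.17, so differences of dim genes lie near background.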

Other observations

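Immunoglobulin genes outside the fixed lists had large differences for both factors. Jchain, which joins secreted IgM and IgA, had a log2 difference of -2.78 (SE 0.43, adjusted p = 0.0597) between genotypes over both treatments and one of 1.93 (SE 0.43, adjusted p = 0.258) for NAC over both genotypes. Its mean log2 signal was 5.52 ± 0.33 (SD, n = 3) in wild-type mock, 2.66 ± 0.31 in mutant mock, 7.37 ± 0.92 in wild-type NAC and 4.67 ± 1.55 in mutant NAC arrays. The mutant mock signal lay under the median gene level of 3.17, so the sizes of its genotype and NAC differences are lower bounds. Ighm, the heavy chain of IgM, had differences of -1.36 (SE 0.31, adjusted p = 0.222) and 1.11 (SE 0.31, adjusted p = 0.401). These genes were singled out after their values were seen, and Jchain passed for the genotype without mutant NAC replicate 1 (adjusted p = 0.00809).

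Mature neutrophil genes fell with the genotype over both treatments by a median of 0.11, with 11 of 14 lower (adjusted p = 0.0176, and adjusted p = 0.339 with an estimated correlation), and rose with NAC over both genotypes by 0.13, with 9 of 14 higher (adjusted p = 0.0497, and adjusted p = 0.403 with an estimated correlation). S100a9 and S100a8, the calprotectin subunits, had genotype differences of -1.19 (SE 0.23) and -1.05 (SE 0.32) and NAC differences of 0.79 (SE 0.23) and 0.94 (SE 0.32), while Cxcr2 differed between genotypes by 0.65 (SE 0.12). The genotype call ended without mutant NAC replicate 1 (adjusted p = 0.115), mutant mock replicate 3 (0.0669, median -0.06), wild-type NAC replicate 3 (0.0524) or wild-type mock replicate 1 (0.0895, median -0.08). It also ended with the filter at the median level (0.135, median -0.45), the filter with trend and robust variance (0.105), array weights (0.0504, median -0.07) and without both arrays that stand apart (0.315, median -0.08). The NAC call ended with a fresh quantile normalization (0.0514), the replicate block (0.0677) and without mutant NAC replicates 2 or 3 (0.0544 and 0.199), mutant mock replicate 3 (0.138, median 0.08), wild-type NAC replicates 1 or 3 (0.124 and 0.0911) or wild-type mock replicates 2 or 3 (0.187 and 0.133). Among lists without a call between genotypes in mock or in NAC, erythroid genes had medians of 0.04 and 0.11, T and NK cell genes -0.07 and -0.09, ribosomal protein genes 0.04 and 0.03, HOX and MEIS genes 0.16 and -0.02, H3K4 methyltransferase genes 0.03 and -0.02, stromal and endothelial genes -0.01 and 0.01, glycolysis and hypoxia genes 0.03 and -0.04, and ATF4 targets -0.02 and 0.01.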
